A study of Homo sapiens with 8 samples.

How the data were processed

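Polyadenylated RNA was sequenced from 8 libraries of cortical neurons made from WTC11, an established human induced pluripotent stem cell line. The cells carried a doxycycline-inducible neurogenin gene, which drives neuronal differentiation, and dCas9-KRAB, a catalytically dead Cas9 joined to a transcriptional repressor. In 4 control libraries the cells had received a non-targeting guide RNA, and in 4 knockdown libraries a guide against UPF1, the central helicase of nonsense-mediated decay (NMD). None of the 8 had a TDP-43 knockdown, per the labels. RNA was isolated with a column kit and a DNase step, and libraries were made with a stranded TruSeq mRNA kit and read as pairs of 150 bases on Illumina instruments, per the labels' protocols. The labels number the libraries 1 to 4 in each group and do not say that these are separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

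The authors deposited 1 table of estimated counts per transcript, with 245261 transcripts and 8 libraries. The deposited values were whole numbers, so the estimated counts entered the tests with no further rounding. The submitters' processing notes name fastp 0.20.1, STAR 2.7.8a, Salmon 1.4.0 and the genome build GRCh38, without saying which program did which step. The annotation release, the settings of the transcript quantification and any scaling by transcript length are not given in the sources used here. Estimated counts divide reads among overlapping transcripts by a model, and the uncertainty of that division is not part of the table. Transcripts of near-identical genes, of overlapping genes and of 1 gene share reads, so their values are less certain than the spread between libraries shows. All 8 columns were mapped to samples by name.

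Total counts per library ranged from 53427124 to 70607615. Transcript identifiers were matched without version numbers to GENCODE release 29 on GRCh38, which is not known to be the release the authors used. This matched 202698 transcripts, 82.6% of the table, which held 94.2% of all counts. Matched transcripts were summed to 58145 genes. These sums include NMD-annotated transcripts, so a rise of a gene need not be a rise of its coding transcripts. Transcripts without a match were never assigned to a gene and entered only the tests on single transcripts. A gene whose transcripts are partly among them has an incomplete sum, and such genes are described as sums over matched transcripts.

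Genes were filtered with filterByExpr and scaled by TMM, which left 18925 genes. They were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, comparing 4 knockdown with 4 control libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. "Rose" and "fell" refer to this threshold. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Levels are CPM, counts scaled to a common library total, after TMM. The 29 fixed gene lists and 5 sets built from the annotation were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01, and again with an estimated correlation. Each family was adjusted separately. The 5 sets were genes with an annotated NMD transcript, genes with an exon junction over 50 nucleotides after the stop codon of the selected transcript, the fifth of coding genes with the longest 3' UTRs, spliced long noncoding RNA genes, and pseudogenes.

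The groups, tests, gene lists, cell type markers, naming rule and most alternatives were fixed before the data were examined. The naming rule took UPF1 and TARDBP, and then genes past the threshold with a mean of at least 5 CPM, all 4 knockdown libraries on 1 side of all 4 controls, and a symbol that is not a clone name. From these it took the 8 largest rises, the 8 largest falls and the 4 further genes of each direction with the smallest p. From each fixed list it took up to 4 members past the threshold with the smallest p, or the single member with the smallest p where none passed. It also took every tested gene within 250 kb of UPF1. Some genes that the rule took are not reported here.

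Tests on single transcripts and on isoform shares were added after the table was seen to hold transcripts and after gene results had been seen. Transcripts were filtered and tested with edgeR as genes were, which left 69782. Within genes, the summed NMD-annotated counts were divided by the summed protein-coding counts, with 0.5 added to each. The log2 ratio was tested with limma for 3633 genes with a mean of at least 10 counts in both sums. The genes named from this test were the 8 rises and 2 falls with the smallest p among genes with complete sums, a rule set before those values were seen. The share of all counts in each transcript type was compared by a two-sided exact permutation test of the 4 against 4 libraries.

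The fits were tested on simulated counts with 200 genes or transcripts changed by known amounts. In the data 2381 genes and 1724 transcripts passed the threshold. Recovery after adjustment depends on the share that is changed, so it may differ there. In the gene test, 28.8% of genes changed 1.25-fold were recovered, 56.9% of those changed 1.5-fold, 72.7% of those changed 2-fold and 95.1% of those changed 4-fold, with 3 false calls among 18639 genes. The transcript test recovered 0% at 1.25-fold, 2.33% at 1.5-fold, 14.9% at 2-fold and 33.3% at 4-fold, with 2 false calls. The isoform test recovered 0%, 2.04%, 13.0% and 47.6% at the same sizes, with 1 false call. The 4-fold size was added after the low recovery at smaller sizes had been seen.

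The alternatives fixed beforehand were RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a test against a log2 fold change of 0.5, coding genes alone, fry, an estimated correlation, a junction distance of 100 nucleotides, and leaving out each library. Chosen after seeing the data were a restriction to genes with complete sums, offsets for GC content and length, a term for libraries 1 and 3 against 2 and 4, coding genes alone as background of the annotation sets, and all alternatives of the transcript and isoform counts. Complete sums meant that unmatched transcripts beside the gene held at most 10% of the joint count and that the selected coding transcript was present. That limit was picked after counts of genes at several limits had been seen. The restriction was devised after the fit over all matched genes had been seen, was for a time treated as the principal set, and was then returned to an alternative because the design fixed beforehand covers all matched genes.

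The guide sequences were searched in the 206694 spliced transcripts of release 29, and neither had an exact match there. Their genomic positions were not determined here. Between libraries of the same group, the chi-square per degree of freedom ranged from 7.31 to 23.2, so none was treated as a second copy of another. This does not show that they came from separate cultures. Cells with a TDP-43 knockdown were not analysed here.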

Results

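RNA was measured in neurons differentiated from a human stem cell line, in 4 control and 4 UPF1 knockdown libraries. UPF1 is the RNA helicase on which nonsense-mediated decay (NMD) depends, the pathway that removes mRNAs with premature stop codons and some normal mRNAs. The comparison asks which transcripts change in neurons when UPF1 is lowered. Control libraries 1 to 4 held 57888497, 61718347, 70607615 and 60070280 estimated counts. Knockdown libraries 1 to 4 held 58784992, 61321933, 55883845 and 53427124. In a principal component analysis of the genes, the first component held 30.02% of the variance and had all controls on 1 side and all knockdown libraries on the other. Knockdown library 3 stood apart on the second component (39.9, against -20.4 to 9.93 for the other 7), which held 14.8% of the variance.

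UPF1 was lowered in every knockdown library. The gene (ENSG00000005007.12, GRCh38 chromosome 19, 18831938 to 18868236, plus strand) stood at 73.1 ± 3.48 CPM (SD, n = 4) in controls and 40.0 ± 2.06 CPM (SD, n = 4) with the UPF1 guide. That is 54.7% of the control level (log2 fold change -0.87, SE 0.050, edgeR adjusted p = 1.15e-05). Controls 1 to 4 had 75.7, 74.3, 74.4 and 67.9 CPM, and knockdown libraries 1 to 4 had 42.6, 38.8, 40.5 and 38.01 CPM. TARDBP, which encodes TDP-43 and was not targeted, stood at 255 ± 7.46 CPM in controls and 240 ± 3.29 CPM with the UPF1 guide (n = 4 each, log2 fold change -0.089, SE 0.032, edgeR adjusted p = 0.111). The TARDBP difference passed the threshold with DESeq2 (adjusted p = 0.0336). Of 13 tested genes within 250 kb of UPF1, 0 passed the edgeR threshold, 2 had an unadjusted p under 0.05, 1 passed with DESeq2 and 0 with limma-voom. The smallest p belonged to DDX49, an RNA helicase gene that starts 87737 bases downstream of the start of UPF1, with a log2 fold change of 0.21 (SE 0.065, edgeR adjusted p = 0.0657). DDX49 passed with DESeq2 (adjusted p = 0.0352) and, in edgeR, once genes with incomplete sums were left out (adjusted p = 0.0412), and 2 of the 13 passed without knockdown library 3. The other gene with an unadjusted p under 0.05 was GDF1 (log2 fold change 0.26, edgeR adjusted p = 0.121), which overlaps CERS1 and is uncertain for that reason.

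**Figure D1:**
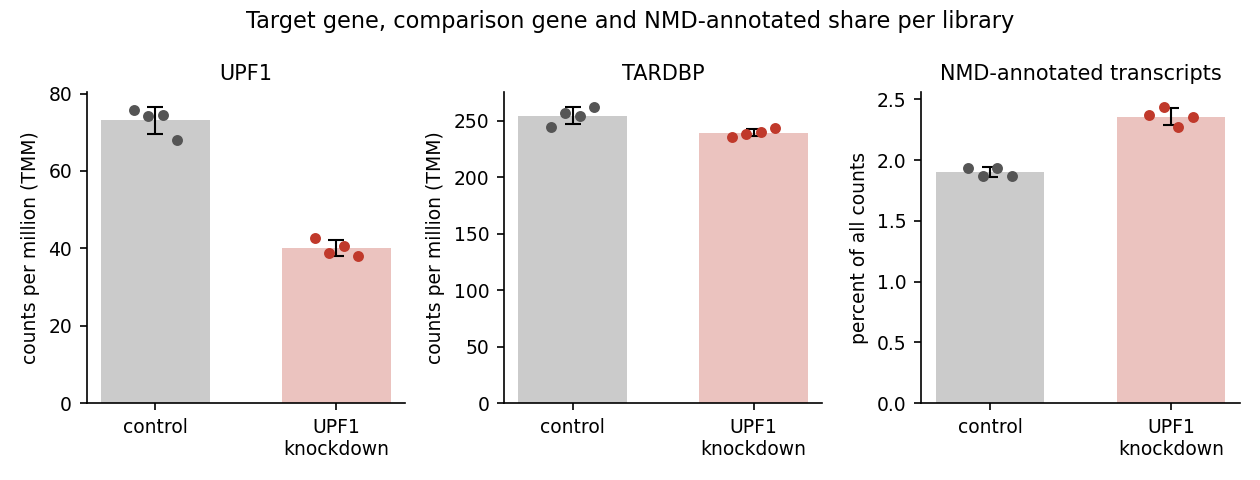
UPF1 and TARDBP in CPM after TMM, and NMD-annotated transcripts as a percent of all counts, in each library (points), with group means (bars) and SD (error bars, n = 4). UPF1 lay between 38.01 and 42.6 CPM in the knockdown libraries and between 67.9 and 75.7 CPM in the controls.

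More genes rose than fell with UPF1 knockdown. Of 18925 genes tested, 2381 passed the edgeR threshold, of which 1722 rose and 659 fell. By at least 2-fold, 297 rose and 30 fell. Among genes with a mean of at least 5 CPM and no overlap between the groups, the largest rise belonged to EPAS1, a hypoxia-inducible transcription factor (chromosome 2, 46293667 to 46386703), from 3.81 ± 0.565 to 36.8 ± 8.56 CPM (SD, n = 4 each, 9.68-fold, log2 fold change 3.27, SE 0.17, edgeR adjusted p = 7.63e-06). Next were the cation channel gene TRPV3 (4.82-fold), the chaperonin pseudogene CCT6P3 (4.78-fold), TYW1B (4.56-fold), the growth factor gene EGF (4.36-fold) and GADD45G of the DNA-damage-inducible GADD45 family (4.09-fold). They were followed by DEK, which encodes a chromatin protein (4.08-fold), and MSH5, of the meiotic mismatch repair family (4.03-fold). Among the other rises with the smallest p were CCDC146 (2.99-fold), the readthrough transcript SUGT1P4-STRA6LP-CCDC180 (3.36-fold), NBPF1 (1.82-fold) and GOLGA6L9 (1.94-fold).

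Under the same conditions, the largest falls included RTL1, an imprinted gene derived from a retrotransposon (chromosome 14, 100879753 to 100903722), from 10.9 ± 2.30 to 3.81 ± 0.881 CPM (SD, n = 4 each, log2 fold change -1.51, SE 0.18, edgeR adjusted p = 0.000582). SELENBP1, which encodes a selenium-binding protein, fell to 0.400 times the control level, and PRDM12, a regulator of sensory neuron development, to 0.427 times. The matrix protein genes SMOC1 and FBLN2 fell to 0.459 and 0.499 times, the ubiquitin ligase gene TRIM56 to 0.502 times, S100B to 0.512 times and the tetraspanin gene TSPAN11 to 0.541 times. PEG10, another imprinted gene derived from a retrotransposon, fell from 3151 ± 129 to 2345 ± 44.5 CPM (SD, n = 4 each, log2 fold change -0.43, SE 0.037, edgeR adjusted p = 7.57e-05). SHISA3 (log2 fold change -0.69) and the transcription factor genes SOX8 (-0.84) and MAF (-0.39) completed the falls with the smallest p.

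In 2266 of the called genes all knockdown libraries lay on 1 side of all controls. Among all tested genes this held for 3477 (18.4%), where chance gives 2.86%. Protein-coding genes made up 1423 of the rises and 627 of the falls. The values for EGF, DEK, MSH5 and RTL1 are sums over matched transcripts only, with 97.7% of the counts near DEK unmatched. CCT6P3, TYW1B, NBPF1 and GOLGA6L9 have near-identical copies elsewhere in the genome and are uncertain for that reason. Of the called genes, 72.3% rose, and with offsets for GC content and length 61.6% did (2011 rose and 1253 fell). DESeq2 gave 1934 rises and 1147 falls, and a term for libraries 1 and 3 against 2 and 4 gave 2225 and 1419. Without knockdown library 2 or 4 the total was 1524 or 1527. The falls numbered 338 without knockdown library 2, 311 without knockdown library 4, 352, 371 and 382 without control 2, 3 and 4, and 1075 without knockdown library 3.

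Lists of classical NMD targets, of noncoding host genes of small nucleolar RNAs and of SR and hnRNP splicing factors were called as higher with the preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.542, 0.481 and 0.756 with an estimated correlation). Of 20 classical NMD target mRNAs, 8 rose and 0 fell, also 8 and 0 adjusted over the list alone, at an unadjusted p under 0.05, with DESeq2 and with limma-voom (camera adjusted p = 0.000868, and adjusted p = 0.542 with an estimated correlation). Examples were RASSF1, a tumour suppressor gene (2.69-fold, log2 fold change 1.43, SE 0.12, edgeR adjusted p = 6.82e-05), TBL2 (1.84-fold), TRA2B (1.62-fold) and the co-chaperone gene BAG1 (1.23-fold, a sum over matched transcripts). Of 19 small nucleolar RNA hosts, 11 rose and 0 fell, also 11 and 0 adjusted over the list alone (camera adjusted p = 6.37e-06, and adjusted p = 0.481 with an estimated correlation). At an unadjusted p under 0.05, 11 rose and 2 fell, and DESeq2 and limma-voom each gave 11 and 0. SNHG12 rose 3.31-fold, SNHG15 2.35-fold, ZFAS1 2.12-fold and SNHG32 2.06-fold, the first 2 as sums over matched transcripts. Matched transcripts gave an incomplete sum for 15 of the 19 hosts, 9 of which rose.

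Of 38 SR and hnRNP splicing factors, 13 rose and 2 fell, and adjusted over the list alone 16 rose and 4 fell (camera adjusted p = 0.000789, and adjusted p = 0.756 with an estimated correlation). TRA2B went from 192 ± 4.78 to 310 ± 23.3 CPM (SD, n = 4 each, log2 fold change 0.69, SE 0.052, edgeR adjusted p = 3.49e-05). TRA2A rose 1.57-fold, RBM39 1.39-fold and SRSF10 1.28-fold. The coding transcripts of RBM39 were not higher (log2 fold change -0.090, and 1.33 for its NMD-annotated ones), while those of TRA2A and SRSF10 were (0.54 and 0.26). The 2 that fell, chosen here after their values were seen, were HNRNPR (log2 fold change -0.18) and HNRNPU (-0.15). Of the 35 divisions of the 8 libraries into 4 and 4, the real one included, 5 gave the splicing factors a p as small, 2 the NMD targets and 1 the small nucleolar RNA hosts. Of 13 NMD factors, 6 rose and 1 fell, and adjusted over the list alone 7 rose and 2 fell (camera adjusted p = 0.0597). With the preset correlation the list was called without control 3 (adjusted p = 0.0364) or knockdown library 2 (0.0446), beside an adjusted p = 0.481 with an estimated correlation over all 8 libraries. The 1 that fell was UPF1 itself, which the guide targeted and which every test of this list included. DHX34 rose 1.63-fold and NBAS 1.17-fold, and SMG5, SMG6 and SMG9, named after their values were seen, also rose (log2 fold changes 0.26, 0.25 and 0.34). In the exon junction complex, the protein assembly that marks spliced junctions for NMD, 2 of 9 rose, also adjusted over the list alone, namely MAGOHB (1.44-fold) and ACIN1 (1.20-fold), and the list was not called (camera adjusted p = 0.921, direction down, median -0.045, mean 0.047). The coding transcripts of MAGOHB and ACIN1 stayed level (log2 fold changes 0.0029 and 0.0058), while their NMD-annotated transcripts were higher (1.13 and 1.00). Among 27 genes of general mRNA decay, 2 rose, also adjusted over the list alone, namely PATL1 (1.30-fold) and PAN3 (1.12-fold), and the list was not called (camera adjusted p = 0.666). PAN3 lost its call without control 1 or 3 or knockdown library 2 or 4 (edgeR adjusted p up to 0.0667).

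Of 19 chaperones, folding enzymes and other genes of the unfolded protein response, 5 rose and 0 fell, and adjusted over the list alone 9 rose and 0 fell. The list was called as higher with the preset correlation (camera adjusted p = 0.0284) and not with an estimated correlation (camera adjusted p = 0.531). The alternative test fry, which does not compare a set with other genes, also called it as higher (adjusted p = 0.0119). At an unadjusted p under 0.05, 9 rose and 1 fell, and DESeq2 and limma-voom each gave 5 and 0. HYOU1 rose 1.15-fold, HSPA5 1.17-fold, CALR 1.19-fold and MANF 1.22-fold, the first 2 as sums over matched transcripts. The list was not called once genes with incomplete sums were left out (camera adjusted p = 0.0798), and 2 of the 35 divisions of the libraries gave it a p as small. HSPA5 lost its call without control 1 or 3 or knockdown library 2 or 4 (edgeR adjusted p up to 0.0824), CALR without control 1, 3 or 4 or knockdown library 1, 2 or 4 (up to 0.0932), and MANF without control 1, 3 or 4 or knockdown library 2 or 4 (up to 0.0996). Of 29 genes of the integrated stress response, 2 rose, STC2 (1.30-fold) and CTH (1.19-fold), against 1 adjusted over the list alone, and the list, with a median log2 fold change of -0.092, was not called (camera adjusted p = 0.0878). It was called as lower without control 2 (adjusted p = 0.0307), control 4 (0.0340), knockdown library 1 (0.00696) or knockdown library 3 (0.0297), and with a term for libraries 1 and 3 against 2 and 4 (0.0164). These calls used the preset correlation (adjusted p = 0.859 with an estimated correlation over all 8 libraries). STC2 lost its call without control 4 or knockdown library 2 (edgeR adjusted p up to 0.0547), and CTH without control 2, 3 or 4 or knockdown library 1, 2 or 4 (up to 0.119). Of 20 p53 targets, 4 rose and 2 fell, and adjusted over the list alone 4 rose and 4 fell (camera adjusted p = 0.822, direction down, median -0.038, mean 0.066). FDXR rose 2.04-fold, SPATA18 1.73-fold and AEN 1.38-fold, and TP53INP1 fell to 0.867 times the control level. The log2 fold change of FDXR was 1.03 for the gene, 0.21 for its coding transcripts and 0.44 for its NMD-annotated ones. Of 20 genes of cholesterol synthesis and uptake, 4 rose and 1 fell, and adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 0.238). MVK rose 1.41-fold, STARD4 rose 1.21-fold, and SC5D fell to 0.881 times. The interferon list had 1 fall in 12 and 0 adjusted over the list alone (camera adjusted p = 0.249).

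Most neuronal genes did not pass the threshold. Of 21 pan-neuronal genes 1 rose, UCHL1 (1.09-fold), and of 28 presynaptic genes 1 fell, the scaffold gene BSN (0.844 times the control level). The counts were the same adjusted over the list alone (camera adjusted p = 0.841 and 0.235). Of 25 postsynaptic genes 2 rose, also adjusted over the list alone, the glutamate receptor gene GRIA1 (1.24-fold) and CAMK2A (3.04-fold, a sum over matched transcripts with 83.4% of the nearby counts unmatched) (camera adjusted p = 0.666). UCHL1 lost its call without control 2, 3 or 4 or knockdown library 1 or 4 (edgeR adjusted p up to 0.0747), and BSN without control 2, 3 or 4 or knockdown library 2 (up to 0.0737). GRIA1 lost it without control 1 or 3 or knockdown library 2 or 4 (up to 0.0761), and CAMK2A without knockdown library 1 (0.0527). Of 10 tested genes of glutamatergic and cortical identity, 3 fell and 0 rose, also adjusted over the list alone. Among them were the transcription factor genes CUX2 (log2 fold change -0.20) and BCL11B (-0.45), and the list was not called (camera adjusted p = 0.0581). With the preset correlation the list was called as lower with a filter of 1 CPM (adjusted p = 0.0273) and with a term for libraries 1 and 3 against 2 and 4 (0.0153), beside an adjusted p = 0.481 with an estimated correlation over all 8 libraries. With the preset correlation it was also called without control 1 (0.0235), control 3 (0.0482), knockdown library 2 (0.0446) or knockdown library 4 (0.0397). BCL11B lost its call without any 1 control or knockdown library 2 or 4 (edgeR adjusted p up to 0.0837). Of 38 axon guidance genes, 5 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.0581). This list was called as lower with the preset correlation without control 1 (adjusted p = 0.0235), control 3 (0.0364) or knockdown library 2 (0.0327), beside an adjusted p = 0.531 with an estimated correlation over all 8 libraries. The ephrin gene EFNA1 rose 1.46-fold, and the receptor genes PLXNA2 and DCC and the ephrin gene EFNA2 fell to 0.798, 0.821 and 0.832 times. Of 15 immediate early genes 2 rose, also adjusted over the list alone, DUSP1 (1.23-fold) and FOSL2 (1.41-fold) (camera adjusted p = 0.666). DUSP1 lost its call without knockdown library 1 or 2 (edgeR adjusted p up to 0.0636), and FOSL2 without control 1, 2 or 3 or knockdown library 2 or 4 (up to 0.0908).

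Few markers of other cell types passed the threshold. Of 16 proliferation markers, 0 passed the edgeR threshold and 0 did so adjusted over the list alone, 4 were lower at an unadjusted p under 0.05, and DESeq2 called 1 and limma-voom 0. The list was nevertheless called as lower (camera adjusted p = 0.0466, median log2 fold change -0.22, and adjusted p = 0.859 with an estimated correlation). The smallest p was that of CDK1 (log2 fold change -0.31, SE 0.11, edgeR adjusted p = 0.104), and the list was not called without knockdown library 1 or 3 or control 2 or 4 (camera adjusted p = 0.196, 0.278, 0.238 and 0.131). Of 12 neural progenitor markers 1 fell, also adjusted over the list alone, the glial and progenitor regulator gene SOX9 (log2 fold change -0.44, camera adjusted p = 0.0970 for the list). The progenitor list was called as lower without control 1 (adjusted p = 0.0387), control 3 (0.0188), knockdown library 2 (0.0327) or knockdown library 4 (0.0138), each with the preset correlation (adjusted p = 0.859 with an estimated correlation over all 8 libraries). Of 11 glial markers 2 fell, among them S100B (log2 fold change -0.97), and adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.432). Of 10 mesenchymal markers 2 fell, FN1 and COL1A2 (-0.53 and -0.44), and adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.748). FN1 lost its call without control 2 or 4 or knockdown library 1, 3 or 4 (edgeR adjusted p up to 0.0846), and COL1A2 without control 1, 2 or 4 or knockdown library 1, 3 or 4 (up to 0.103). The median of the mesenchymal list was positive (0.097) and that of the glial list was 0.020, although the glial mean and test were negative. Of 7 pluripotency markers 1 rose, also adjusted over the list alone, DPPA4 (1.46-fold, camera adjusted p = 0.301). Of 16 inhibitory and peripheral neuron markers 0 passed the edgeR threshold and 0 did so adjusted over the list alone, with 1 lower at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom (camera adjusted p = 0.859, direction down, median 0.0082, mean -0.0096).

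Of 81 ribosomal protein genes 1 rose and 2 fell, and adjusted over the list alone 1 rose and 0 fell, with a median log2 fold change of -0.062 (camera adjusted p = 0.00309, and adjusted p = 0.859 with an estimated correlation). RPS23 fell to 0.910 and RPL14 to 0.935 times the control level, and RPS27 rose 1.89-fold as a sum over matched transcripts, with 96.4% of the nearby counts unmatched. The list was not called without knockdown library 3 (camera adjusted p = 0.483) or control 2 (0.102). RPS23 lost its call without control 2 or 4 or knockdown library 1, 2 or 4 (edgeR adjusted p up to 0.0639), and RPL14 without any 1 control or knockdown library 1, 2 or 4 (up to 0.140). RPL14 also lost it once genes with incomplete sums were left out (edgeR adjusted p = 0.0729). Of 35 divisions of the libraries into 4 and 4, 21 gave the ribosomal list a p as small, 16 gave the proliferation list one, and 16 gave one to the long 3' UTR set described next. Of 13 mitochondrial mRNAs 0 passed the edgeR threshold, at an unadjusted p under 0.05, adjusted over the list alone, with DESeq2 or with limma-voom (camera adjusted p = 0.321), and MT-CO2 had the smallest p (log2 fold change 0.18, edgeR adjusted p = 0.416). The mitochondrial list was called with the preset correlation without knockdown library 2 (camera adjusted p = 0.0327, beside an adjusted p = 0.906 with an estimated correlation over all 8 libraries). Of 20 selenoprotein genes, TXNRD2 rose (2.47-fold) and SELENOP fell (0.516 times), against 2 that rose and 1 that fell adjusted over the list alone (camera adjusted p = 0.822, direction down, median -0.027, mean 0.033). Both stood below 1 CPM. TXNRD2 lost its call without control 2 or 4 or knockdown library 1, 2 or 4 (edgeR adjusted p up to 0.10), and SELENOP without control 1, 2 or 3 or knockdown library 1 or 4 (up to 0.0701). Of 21 genes with cryptic exons after TDP-43 loss, ATG4B rose (1.11-fold) and PXDN fell (0.831 times), also adjusted over the list alone (camera adjusted p = 0.0597). This list was called as lower without control 1 (adjusted p = 0.0348), knockdown library 1 (0.0497) or knockdown library 3 (0.0498), each with the preset correlation (adjusted p = 0.531 with an estimated correlation over all 8 libraries). The call of ATG4B was lost without control 1, 3 or 4 or knockdown library 1, 2 or 4 (edgeR adjusted p up to 0.121). Of 9 RNA-binding protein genes linked to amyotrophic lateral sclerosis, TIA1 rose (1.16-fold) and TAF15 fell (0.873 times), also adjusted over the list alone (camera adjusted p = 0.235). The fixed list of UPF1 neighbours had 8 tested genes, 0 past the edgeR threshold and 0 adjusted over the list alone, 2 higher at an unadjusted p under 0.05, and 1 by DESeq2 and 0 by limma-voom (camera adjusted p = 0.859).

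Genes able to make an annotated NMD transcript and pseudogenes were called as higher with the preset correlation, with rises in a minority of their members. Their median log2 fold changes were 0.025 and 0.074. Of 6208 genes with an annotated NMD transcript, 880 rose (14.2%, against 6.62% of other genes) and 173 fell (camera adjusted p = 0.00156, and adjusted p = 0.0807 with an estimated correlation). Of 838 pseudogenes, 151 rose (18.02%, against 8.69% of other genes) and 3 fell (camera adjusted p = 0.000832, and adjusted p = 0.0271 with an estimated correlation). Among the 29 lists and 5 sets, the call for pseudogenes was the only 1 that held with an estimated correlation. Of 2970 genes with the longest 3' UTRs, over 2790 nucleotides, 196 rose (6.60%, against 9.56%) and 205 fell (6.90%, against 2.85%), and the set was called as lower (camera adjusted p = 0.00140, and adjusted p = 0.375 with an estimated correlation). Of 51 genes with an exon junction after the stop codon 9 rose and 2 fell (camera adjusted p = 0.0815), and the set was called with the preset correlation without control 1 (adjusted p = 0.0328) or control 3 (0.0261), beside an adjusted p = 0.375 with an estimated correlation over all 8 libraries. Of 1950 spliced long noncoding RNA genes 127 rose and 17 fell (camera adjusted p = 0.535).

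At the level of single transcripts, the rises were concentrated in NMD-annotated transcripts and pseudogenes. Of 5638 NMD-annotated transcripts 422 rose and 5 fell, with a median log2 fold change of 0.38. Of the 422, 16 had no count in any control. With these at their lower bounds the median was still 0.38, which 16 of 5638 values could hardly move. This compares with 402 rises and 313 falls among 35667 protein-coding transcripts. NMD-annotated transcripts were called as higher (camera adjusted p = 4.86e-13, and adjusted p = 0.00171 with an estimated correlation) and protein-coding ones as lower (adjusted p = 0.000400, and adjusted p = 0.00545 with an estimated correlation). Camera compares a type with all other tested transcripts, so the call of protein-coding ones is relative to a background that holds the rising types. Protein-coding transcripts had more rises than falls and a median log2 fold change of -0.049. Retained-intron transcripts, which keep part of an intron, had 67 rises and 6 falls of 8673 and were not called (camera adjusted p = 0.636). Pseudogene transcripts had 107 rises and 1 fall of 1252, and noncoding isoforms of coding genes 149 rises and 3 falls of 5072 (camera adjusted p = 0.000120 and 0.0156, and adjusted p = 0.00171 and 0.00545 with an estimated correlation). Long noncoding RNA transcripts had 70 rises and 3 falls of 3682 (camera adjusted p = 0.996). NMD-annotated transcripts took 1.90% ± 0.0400 of all counts in controls and 2.36% ± 0.0698 in knockdown libraries (SD, n = 4 each, exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give, adjusted p = 0.0571 over 8 types). The count of NMD-annotated transcripts that rose was 281, 266, 244 and 262 without control 1, 2, 3 and 4, and 201, 180 and 200 without knockdown library 1, 2 and 4.

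**Figure D2:**
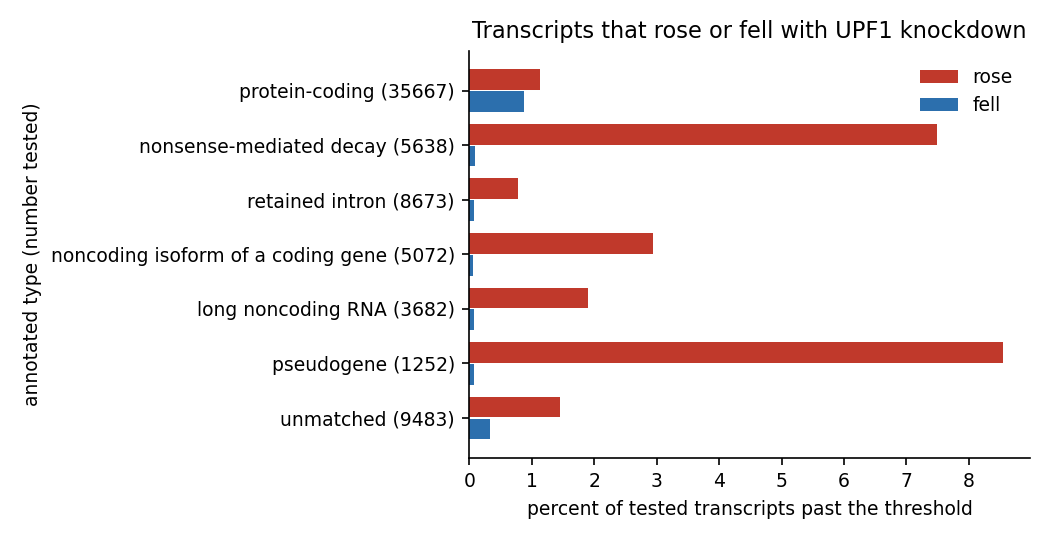
Percent of tested transcripts of each annotated type that rose (red) or fell (blue) with UPF1 knockdown, by edgeR over 4 against 4 libraries, with the number tested in brackets. Of NMD-annotated transcripts 7.48% rose and 0.0887% fell.

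Within single genes, the balance between isoforms moved toward the NMD-annotated ones. The ratio of NMD-annotated to protein-coding counts rose in 498 of 3633 genes and fell in 5 (limma, Benjamini-Hochberg). In the 498, NMD-annotated transcripts had a median log2 fold change of 1.48 and protein-coding ones of -0.028, and the coding mean was lower in 286. The splicing factor gene HNRNPM had an NMD-annotated share of 3.23% ± 0.371 in controls and 16.5% ± 0.638 with knockdown (SD, n = 4 each, log2 ratio change 2.57, SE 0.098, limma adjusted p = 1.88e-05). HNRNPL went from 2.84% ± 0.711 to 21.1% ± 2.39, and SRSF2 from 4.76% ± 0.368 to 31.1% ± 4.96 with a coding log2 fold change of -0.63. PRPF39, a splicing factor gene, went from 64.5% ± 1.34 to 85.2% ± 1.53, and the translation factor genes EIF4A2 and EEF1B2 from 21.9% ± 1.10 to 42.3% ± 2.93 and from 0.426% ± 0.0473 to 4.84% ± 0.768. PPP4R3A went from 3.27% ± 0.158 to 8.55% ± 0.600. ANXA5, a phospholipid-binding protein gene, had 0 NMD-annotated counts in the controls, which allows a share of up to 0.0181% (3 counts over the group, counting error only), and 1.08% ± 0.326 with knockdown, an NMD-annotated level at least 59.6-fold higher. The falls with the smallest p were in ITGB3BP (78.3% ± 1.04 to 70.0% ± 1.66) and NAIP (2.28% ± 0.575 to 0.622% ± 0.331), and NAIP has near-identical copies that make it uncertain.

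Of 30 SR and hnRNP genes with both kinds of transcript, the ratio rose in 20 and fell in 0, and the coding mean was lower in 12 of the 20. Over all 30 the median coding log2 fold change was -0.038, so a lower coding mean was not particular to the 20. Without knockdown library 2 or 1 the count of 498 was 293 or 311.

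**Figure D3:**
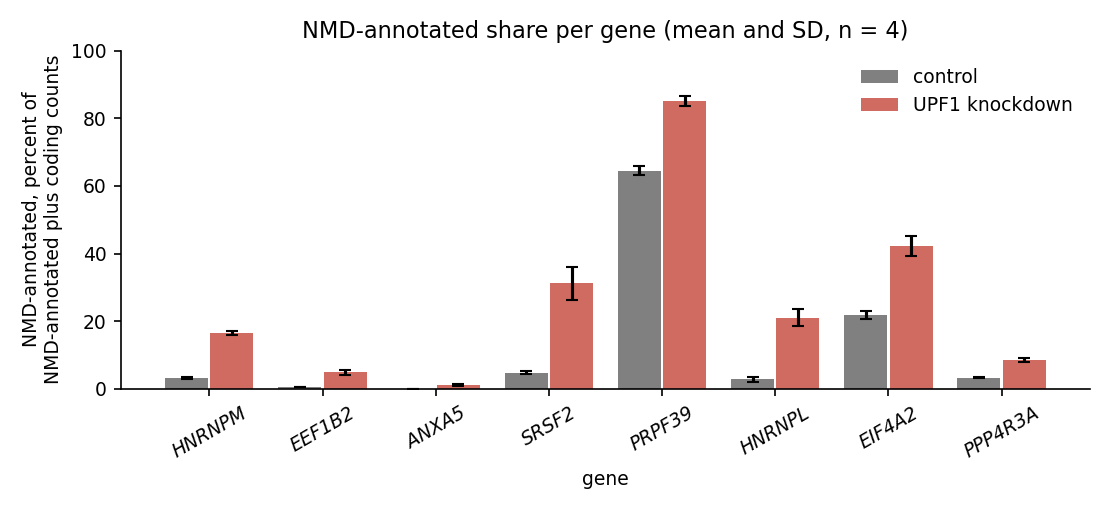
NMD-annotated counts as a percent of NMD-annotated plus protein-coding counts in the 8 genes whose ratio rose with the smallest p among genes with complete sums, in control (grey) and UPF1 knockdown (red) libraries, as means with SD (error bars, n = 4 per group). SRSF2 went from 4.76% to 31.1% and PRPF39 from 64.5% to 85.2%.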

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

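None of the results given here was weighed with a test chosen after it was seen. Of 222 groups of 4 libraries examined, 9 had 1 library far from the other 3, judged by its gap to the nearest of them as a share of the group's range. Chance gives about 1 in 20 groups, which is 11.1 here. Among controls, library 2 was apart for TRPV3 (2.53 CPM, the other 3 from 2.02 to 2.05) and RTL1 (14.3 CPM, the others from 9.38 to 10.1), library 3 for PATL1 (43.8 CPM, the others from 42.8 to 42.9) and library 4 for DDX49 (29.7 CPM, the others from 31.9 to 32.1). In the knockdown group, library 1 was apart for PEG10 (2279 CPM, the others from 2361 to 2373), library 4 for PXDN (142 CPM, the others from 129.5 to 131) and library 3 for COPE (33.9 CPM, the others from 42.2 to 42.8). The noncoding isoforms of coding genes took 1.32% of the counts in knockdown library 3 and 1.39% in each of the others, to 3 digits. Pseudogenes took 0.410% of the counts in control 4 and 0.431% to 0.434% in the other controls.

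Transcripts with no match in the annotation entered no gene, and 137 of the 9483 tested rose while 32 fell (edgeR, Benjamini-Hochberg). No biological explanation was tested for them.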

How the results depend on the processing

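The settings named here as complete sums, GC content and length offsets and the term for libraries 1 and 3 against 2 and 4, and every alternative of the transcript and isoform counts, were chosen after the data had been seen. Apart from leaving out libraries, 1061 values of single genes and lists and 132 of the principal results kept their direction and their side of the threshold or stayed within 1.5 times. Of the others, 11 values of single genes and lists fell short of the threshold, 25 came to pass it and 7 changed direction, and of the principal results 15 fell short of the threshold and 21 counts moved by over 1.5 times. UPF1 stayed lower and past the threshold under all alternatives run on it. Where the alternative tests fewer or different genes its construction may account for part of a change (with coding genes alone, 173 rises of at least 2-fold), and otherwise the cause was not tested.

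DESeq2 gave 1147 falls and 1 UPF1 neighbour, and offsets for GC content and length 1253 falls and 2 neighbours. With RLE the proliferation list had an adjusted p of 0.0506. A filter of 1 CPM gave 17 falls of at least 2-fold, an adjusted p of 0.0564 for proliferation, the opposite direction for the mesenchymal (0.768) and inhibitory and peripheral (0.994) lists, and a call for glutamatergic and cortical identity (0.0273, beside an adjusted p = 0.481 with an estimated correlation over all 8 libraries). With complete sums 1 neighbour passed, the adjusted p was 0.0501 for proliferation and 0.0798 for the unfolded protein response, and the exon junction complex (0.896) and pan-neuronal (0.805) lists changed direction. Against a log2 fold change of 0.5, 292 genes passed, of which 274 rose and 18 fell, 11 of them by at least 2-fold. With an estimated correlation 0 lists and 1 annotation set were called in camera. The adjusted p was then 0.542 for NMD targets, 0.481 for small nucleolar RNA hosts, 0.756 for splicing factors, 0.531 for the unfolded protein response, 0.859 for ribosomal proteins and for proliferation, 0.0807 for genes with an NMD transcript and 0.375 for the longest 3' UTRs. All other alternatives of camera used the preset correlation. fry, which does not compare a set with other genes, gave 0.596 for ribosomal proteins, 0.528 for proliferation and 0.241 for the longest 3' UTRs, and the opposite direction for the exon junction complex (0.367), p53 targets (0.994) and general mRNA decay (0.994). It passed NMD factors (0.0119), glutamatergic and cortical identity (0.00558), TDP-43 cryptic exon genes (0.0308), glial markers (0.0403), and the sets with a junction after the stop codon and of spliced long noncoding RNAs (both 0.0301). It kept the calls of NMD targets and the unfolded protein response (both 0.0119), small nucleolar RNA hosts (0.00207) and splicing factors (0.01615). Of the sets it kept genes with an NMD transcript (0.00230) and pseudogenes (4.18e-05). The term for libraries 1 and 3 against 2 and 4 gave 3644 genes, with 1419 falls, and called the integrated stress response (0.0164) and glutamatergic and cortical identity (0.0153) as lower (adjusted p = 0.859 and 0.481 with an estimated correlation and no such term).

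With the replicate number as a block, 4127 genes passed, 1757 of them falls, with 2 neighbours, 11 lists (the 5 more being NMD factors, 0.0361, the integrated stress response, 0.0129, glutamatergic and cortical identity, 0.0186, TDP-43 cryptic exon genes, 0.0412, and neural progenitor markers, 0.0361), 59 NMD-annotated transcripts that rose and 304 genes whose NMD-annotated share rose. For those 5 lists the adjusted p was 0.481, 0.859, 0.481, 0.531 and 0.859 with an estimated correlation and no block. The correlations of same-numbered libraries were 0.0966, 0.0873, 0.0780 and -0.012, so the numbers were not taken to pair the libraries. Libraries 1 to 3 of each group correlated best with their own number, and both libraries numbered 4 correlated best with number 2.

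Without 1 library, 1524 to 3214 genes passed, 311 to 1075 fell, 0 to 2 neighbours passed, and 5 to 11 lists were called. NMD-annotated transcripts that rose numbered 180 to 303, and genes whose NMD-annotated share rose 293 to 482. The adjusted p ranged from 6.45e-07 to 0.483 for ribosomal proteins, from 0.00108 to 0.278 for proliferation, from 0.837 to 0.983 for the exon junction complex, from 0.622 to 0.967 for p53 targets and for selenoproteins, from 0.637 to 0.967 for inhibitory and peripheral markers, from 0.382 to 0.967 for pan-neuronal genes, from 0.0327 to 0.929 for mitochondrial mRNAs and from 0.383 to 0.968 for the list of UPF1 neighbours. Log2 fold changes near 0 changed sign in COPE (-0.035 to 0.071), TMEM59L (-0.030 to 0.065) and ARMC6 (-0.044 to 0.059). Of 79 genes called and reported, 59 kept the call without every single library in turn. On simulated counts the transcript test recovered 33.3% of 4-fold changes, and recovery was not divided by count.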

Other observations

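Chosen after the result was seen were the tests of pseudogene parents, of length and GC content, of retained introns, the comparisons of proliferation scores and of proliferation with mesenchymal markers, and the transcripts named next. The count of library divisions for each single list, set and type was added after the numbers of lists, sets and types called per division had been seen, and before its own outcome was. Over all genes tested, the ratio of NMD-annotated to coding counts rose in 13.7%, and whether any list differed from that share was not tested. Of 24 ribosomal protein genes with both kinds of transcript, it rose in 8 and fell in 0 (limma, Benjamini-Hochberg), and the coding mean was lower in all 8. Over all 24 the median coding log2 fold change was -0.10, so a lower coding mean was not particular to the 8. The ratio rose in 3 of 8 cholesterol genes, 3 of 10 genes of the integrated stress response and 2 of 2 genes of the exon junction complex. It passed the limma threshold in 0 of 10 genes of general mRNA decay, 0 of 7 presynaptic, 0 of 6 pan-neuronal and 0 of 4 selenoprotein genes, where 2, 0, 1 and 0 had a higher ratio at an unadjusted p under 0.05. Among single NMD-annotated transcripts, ENST00000403542.6 of RBM39 went from 44.4 ± 3.14 to 108.8 ± 7.99 CPM, ENST00000526015.5 of TAF1D from 7.97 ± 0.740 to 39.2 ± 7.43 CPM, and ENST00000477442.6 of the splicing factor gene SRSF3 from 19.4 ± 2.58 to 65.8 ± 7.85 CPM (SD, n = 4 each; edgeR adjusted p = 0.000612, 0.000908 and 0.00131).

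Of the 35 divisions of the 8 libraries into 4 and 4, only the real one gave as many genes (2381, highest other 55). The same held for transcripts (1724, highest other 5) and genes with a changed isoform ratio (503, highest other 3). Each is 1 of 35, the smallest share that 35 divisions can give. Every other division mixes knockdown and control libraries, which widens the spread within its groups. The gaps to the other divisions therefore cannot be weighed beyond that rank. Chance cannot be excluded for the number of lists called (6, highest other 10, with 16 divisions giving as many), of annotation sets (3, highest other 4, with 8) or of transcript types (4, highest other 4, with 3). By the unadjusted camera p, the real division came first for the small nucleolar RNA hosts (2.20e-07, lowest other 3.52e-05) and genes with an NMD transcript (0.000936, lowest other 0.00105). It also came first for NMD-annotated transcripts (6.08e-14, lowest other 1.10e-07), noncoding isoforms (0.00778, lowest other 0.0413) and pseudogene transcripts (3.00e-05, lowest other 0.00754). Each is 1 of 35, with no adjustment over the lists, sets and types examined, so chance is not excluded for them. These p-values use the preset correlation, and camera with an estimated correlation lost the calls of the hosts and of genes with an NMD transcript (adjusted p = 0.481 and 0.0807). Both passed in fry (adjusted p = 0.00207 and 0.00230). Chance also cannot be excluded for NMD targets (8.98e-05, lowest other 3.00e-05), the unfolded protein response (0.00489, lowest other 0.00124), pseudogenes (0.000166, lowest other 0.000105) and protein-coding transcripts (0.000150, lowest other 8.18e-05), each 2 of 35, or for splicing factors (5.44e-05, lowest other 9.51e-07, 5 of 35). Nor can it be for ribosomal proteins (0.000427, lowest other 8.05e-34, 21 of 35), proliferation markers (0.00963, lowest other 1.50e-16, 16 of 35) and the longest 3' UTRs (0.000558, lowest other 1.50e-16, 16 of 35), where p-values this small in other divisions point to a structure of the libraries that does not follow the groups.

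Pseudogenes rose at 18.02%. Low counts alone are argued against, since the highest of 1000 draws of protein-coding genes matched on mean count reached 10.9%. Reads shared with parent genes are argued against, as a set, for the 74 risers with a tested parent of the same symbol. Their parents had a median log2 fold change of 0.065 (SE 0.017) beside 1.06 for the pseudogenes. Of these parents 21 rose and 7 fell, against 1722 and 659 of all 18925 genes tested, so shared reads stay open where the parent rose. They cannot be told apart for the 77 without a tested parent. Decay of spliced pseudogene RNA through UPF1 is a candidate explanation, as 26.2% of the 538 pseudogenes with several exons rose and 3.33% of the 300 with a single exon did (Fisher's exact p = 1.39e-19, two-sided). Pseudogenes with several exons and with a single exon were not matched on mean count, so this comparison cannot separate decay from a difference in level. Decay remains a hypothesis, and the sharing of reads stays open for the 77 and for those whose parent rose.

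NMD-annotated transcripts rose with a median log2 fold change of 0.38. Length and GC content are argued against, since the highest median over 1000 draws of other transcripts matched on length, GC content and mean count was 0.0072. An equal shift of reads to minor isoforms is argued against for retained introns only. In 1552 pairs from 1082 genes NMD-annotated transcripts exceeded retained-intron transcripts of similar count by a median of 0.51 (SE 0.045). This comparison was chosen after the result was seen. Noncoding isoforms of coding genes (149 rises and 3 falls of 5072, median log2 fold change 0.099) were not compared in this way. A shift to them stays open. Reduced decay with less UPF1 may account for the rise of NMD-annotated transcripts, as a hypothesis, and errors in how the authors' model divided reads among isoforms were not tested.

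The proliferation markers were called as lower with the preset correlation (camera adjusted p = 0.0466) and not otherwise (adjusted p = 0.859 with an estimated correlation). Over all 8 libraries the scores of the groups overlapped (difference -0.19, exact permutation p = 0.343), but they did not overlap within libraries 1 and 3 (difference -0.19) or within libraries 2 and 4 (-0.20). Within these strata, which were noticed in the same scores, the exact permutation p was 0.0556, the smallest that their 36 arrangements can give, so fewer dividing cells in the knockdown libraries may account for the lower list and stay open. A lower share of every other cell type also stays open, since the mesenchymal median exceeded the proliferation median by 0.32 with an SE of 0.17. The difference between libraries 1 and 3 and libraries 2 and 4 (-0.44) was first tried as an explanation and dropped because both groups hold both kinds of library, and with a term for it the list had a camera adjusted p of 7.71e-05, again with the preset correlation.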
